A study of Rattus norvegicus with 2 samples.

How the data were processed

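Nuclear RNA of the orbitofrontal cortex of male Sprague-Dawley rats was measured in 2 single-nucleus libraries, 1 from animals given methamphetamine (METH) and 1 from animals given saline. Per the labels' protocols, nuclei were taken from detergent-lysed, dounced tissue, made into libraries with the Chromium Next GEM Single Cell 3' v3.1 chemistry and sequenced on an Illumina NovaSeq. The deposited matrices hold raw UMI counts per gene and nucleus barcode, made with Cell Ranger 7.0.0 per the file headers. The genes carry rat Ensembl identifiers, per the deposited gene tables. Per the submitters' processing notes the build was hg38, a human build that the rat identifiers do not match. The rat build and the annotation release are not given in the sources used here. Gene symbols were taken from the deposited gene tables alone, and listed genes whose symbol is missing there were not measured.

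Barcodes with at least 500 genes and at most 5% mitochondrial UMIs were kept. Doublets were called in each library with Scrublet in scanpy 1.11.5, at an expected rate of 0.06, and were removed. This left 5159 of 5543 METH nuclei, with 328 doublets removed (5.98%), and 6509 of 6969 saline nuclei, with 401 removed (5.80%). Counts were scaled to 10000 per nucleus and log-transformed. Variable genes (2000, chosen within each library), 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) were used on both libraries together with no integration. Clusters were named from fixed marker genes, as X-like classes written below without the suffix. The cluster naming thresholds were set after the clusters' markers were seen and before the libraries were compared. A cluster took a class where its mean marker level reached 0.4 of the highest cluster's level, and a class counted as present only where some cluster reached 0.6. A cluster at 0.4 for 2 unrelated classes counted as mixed, and shallow clusters without a marker among their top genes were left without a name. A cluster with over 90% of its nuclei from 1 library, after scaling to library size, was left without a name. Neurons were clustered again at resolution 0.5 for subclasses, and a subclass name needed a level of 0.4 and a lead of 0.2 over the next subclass.

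With 1 library per group there is no spread between samples, so no test was made and no p-value is given. UMIs were summed over the nuclei of a class in each library and scaled to the usual CPM unit by that sum. Ratios are log2 METH over saline with the exact conditional 95% binomial interval, and shares of nuclei have exact Clopper-Pearson 95% intervals. These intervals cover counting error only, and the 4 animals of each group cannot be separated. Classes with at least 50 nuclei in each library were compared. A gene was measured in a class with at least 100 UMIs over both libraries and 20 CPM in either. A gene was called higher or lower where its ratio and the interval bound nearest to 0 both passed 1.5-fold. Before the data were examined, the filters, the measures, the size rule, 36 gene lists, the marker genes, the rule for naming genes and the first set of alternatives were fixed.

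Genes were named by this rule: in each class the 4 highest and the 4 lowest in METH by the interval bound nearest to 0, among genes that reach at least 0.2 of their highest class level. Mitochondrial, ribosomal protein and haemoglobin genes and clone-based names were left out of it. Up to 10 genes per direction past the size rule in at least 3 classes were added, and the 2 to 4 members of a described list with the largest absolute log2 ratio. List medians were placed among 10000 random lists matched on mean CPM in 20 bins, as a description of these libraries. Intervals of list medians come from 1000 Poisson redraws of the class sums.

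The lists described, and those treated as leading, were picked from the 36 fixed lists after their values were seen. The size rule was tested on simulated data drawn from the class means and library sizes, with 200 genes changed. In excitatory neurons (7060 genes) it recovered 100% of the genes changed 2-fold or 3-fold, and in astrocytes (4720 genes) 64.1% and 98.3%. In mural nuclei (707 genes) it recovered 45.8% and 98.1%. Of genes changed 1.5-fold it called 2.99%, 3.08% and 3.08% in these classes, and it called 0 unchanged genes. In excitatory neurons 95.4% of the intervals held the true ratio, in astrocytes 95.8% and in mural nuclei 94.6%. The simulated counts were Poisson draws with no spread between nuclei, animals or libraries. Coverage near 95% and the lack of false calls were therefore built in, and the simulation covers counting error alone.

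The alternatives fixed at the same time were no doublet removal, at least 200 or 1000 genes per nucleus, at most 1% mitochondrial UMIs, centring on each library before clustering, Leiden resolutions of 0.5 and 2, and shares among neurons or among non-neuronal nuclei. They also included scaling with edgeR 4.0.16 TMM factors, equal weight per nucleus, thinning to 1000 UMIs, at least 30 UMIs with no CPM minimum, a 2-fold size and the mean of list members. Chosen after the data were seen were nuclei matched on UMIs within a class (equal numbers per library in 20 bins of log UMIs), neuron clusters weighted alike in both libraries, a total without the most abundant gene, each gene without its highest nucleus, a cluster mostly of 1 library counted as inhibitory neurons, and subclasses named with no lead needed. Thinning to 1000 UMIs left out 161 METH and 273 saline nuclei. The matched medians first used the members measured in the matched nuclei and were switched to the members of the unmatched comparison after both versions had been seen, which moved the immediate early median in excitatory neurons toward 0. A few genes that the naming rule picks are not reported here. Microglia, fibroblasts and committed oligodendrocyte precursors had too few nuclei for a comparison of expression.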

Results

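Nuclei of the orbitofrontal cortex, a prefrontal region involved in value and choice, were profiled after repeated METH, a psychostimulant that releases dopamine. Rats of 8 weeks received 1 mg/kg METH or saline for 7 days, in a model of behavioural sensitization. Per the labels, tissue of 4 animals per group was taken and 1 library per group was made; how the animals were combined is not given in the sources used here. The METH library held 5543 barcodes with 44969322 UMIs and medians of 6401 UMIs and 2983 genes per nucleus. The saline library held 6969 barcodes with 42221257 UMIs and medians of 4992 UMIs and 2582 genes. A single gene, AC134224.3 (ENSRNOG00000062158), took 6.82% of the METH UMIs and 5.12% of the saline UMIs. No replicates exist, so each value below describes these libraries.

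The first comparison asked which cell classes made up each library. Excitatory neurons, the glutamatergic projection cells, were 41.6% of the METH nuclei and 53.5% of the saline nuclei, a log2 ratio of -0.36 (interval -0.44 to -0.29). Inhibitory neurons, which release GABA, were 1290 of 5159 METH nuclei and 18.8% of the saline nuclei, a log2 ratio of 0.41 (0.30 to 0.53). Astrocytes (8.26% and 8.02%), oligodendrocytes (5.54% and 5.73%), oligodendrocyte precursors (2.64% and 2.78%), endothelial nuclei (2.83% and 2.52%) and mural nuclei (1.98% and 1.94%) differed by less than their counting error. With at least 1000 genes per nucleus the astrocyte log2 ratio was 0.21, with an interval above 0 (0.0075 to 0.41). Microglia, the resident immune cells, were at 0.74% and 1.17%, a log2 ratio of -0.66 (-1.27 to -0.08), but of -0.47 with an interval that held 0 (-1.09 to 0.13) at a limit of 1% mitochondrial UMIs. These shares rest on 38 and 76 nuclei. They leave out an unnamed cluster with the same 10 highest genes, described below, which held 3.74% and 3.70% of the nuclei. Fibroblasts were at 0.81% and 0.28%, a log2 ratio of 1.56 (0.73 to 2.44), from 42 and 18 nuclei. Committed oligodendrocyte precursors (25 and 19 nuclei) did not differ beyond counting error.

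**Figure D1:**
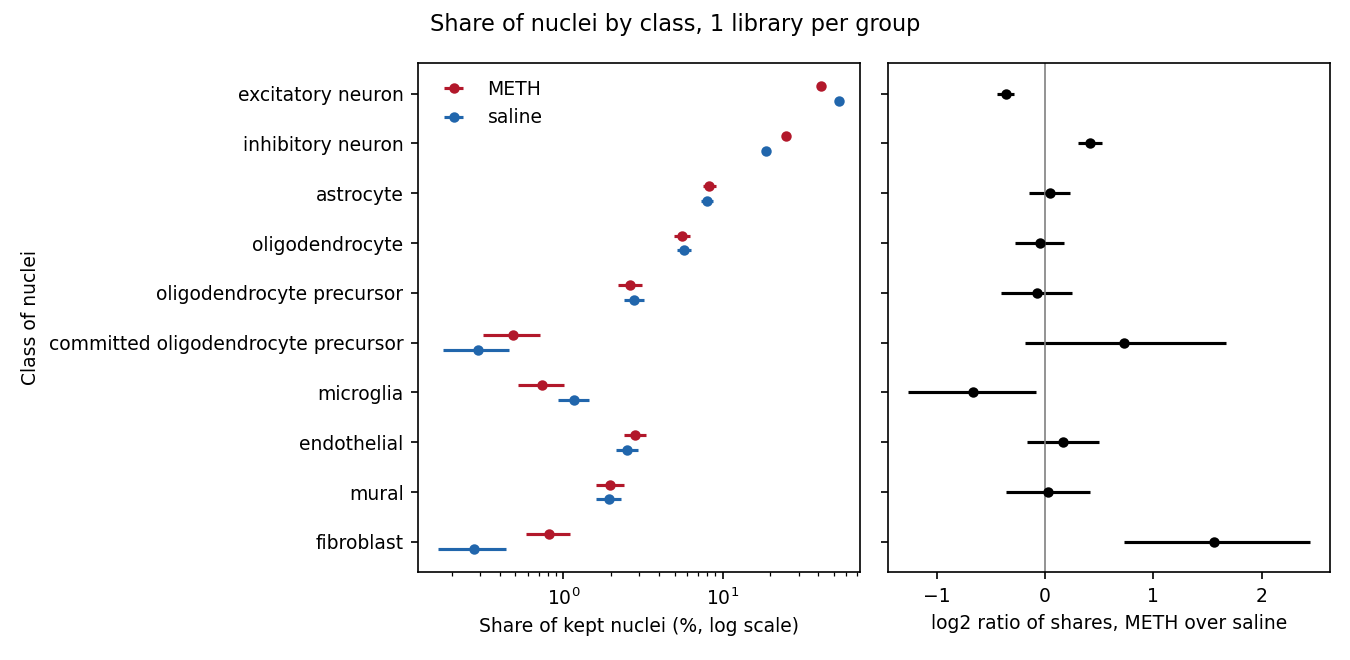
Share of kept nuclei per class in each library (left, percent on a log axis, exact 95% intervals) and the log2 ratio of the shares, METH over saline (right, exact 95% intervals). Excitatory neurons lie at -0.36 and inhibitory neurons at 0.41, while the intervals of astrocytes and oligodendrocytes hold 0.

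Within the excitatory neurons, subclasses took uneven shares. Layer 5/6 near-projecting neurons were 237 of 2145 METH excitatory nuclei and 6.06% of the saline ones (log2 ratio 0.87, 0.59 to 1.14), and named layer 2/3 intratelencephalic neurons 30.5% and 23.4% (0.38, 0.23 to 0.53). Layer 4/5 intratelencephalic neurons were 8.86% and 10.9% (-0.30, -0.56 to -0.04). An excitatory cluster left without a subclass name was 7.04% and 13.5% (-0.94, -1.21 to -0.67); its closest subclasses were layer 2/3 at a marker level of 0.585 and layer 4/5 at 0.413. With clusters named from this level alone, a choice made after the data were seen, layer 2/3 neurons were 37.5% and 36.9% (0.024, -0.10 to 0.15), so their difference rests on this cluster, and layer 4/5 neurons 21.8% and 27.6% (-0.34). Among inhibitory nuclei, the Sst subclass was at 28.1% in both libraries and the Pvalb subclass at 30.8% and 32.8%. The Sncg subclass was at 9.61% and 6.79% (0.50, 0.088 to 0.92), and Lamp5 nuclei were 106 of 1290 and 128 of 1222 (-0.35, -0.74 to 0.032). Nuclei in clusters without a name were 10.1% of the METH and 4.98% of the saline nuclei. A cluster with GABAergic markers, whose highest genes included Meis1, Pbx3 and Cdhr1, held 142 METH nuclei and 1 saline nucleus. Another, with Bnc2 and Cdh19 among its highest genes, held 33 and 3. The remaining unnamed clusters held 155 and 79 nuclei, and 193 and 241. The highest 10 genes of the latter, among them Ctss and Ikzf1, were also those of the microglia cluster, but its closest class was excitatory neurons, at a marker level of 0.374, and its median was 12628 UMIs against 1264.5 in that cluster.

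Depth differed between the libraries in each of the 7 compared classes. Excitatory neurons had medians of 9395 UMIs in METH and 6412.5 in saline, inhibitory neurons 6107 and 4368, astrocytes 2419.5 and 2011.5, and oligodendrocytes 2074 and 1555. Genes per excitatory nucleus were 3638 and 2975. After thinning each nucleus to 1000 UMIs they were 751 and 761, and in oligodendrocytes 638 and 704 in place of 1126 and 1009.

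In excitatory neurons, immediate early genes, which neuronal activity induces within minutes, took a lower share of UMIs in the METH library. All 16 measured members lay below 0, with a median log2 ratio of -0.24 (-0.33 to -0.20) at percentile 0 of the random lists. Fosb was at 15.5 CPM in METH and 22.9 in saline (-0.56), Gadd45g at 15.0 and 21.7 (-0.53), the synaptic plasticity gene Arc at 45.8 and 65.4 (-0.51) and Egr1 at 41.1 and 58.0 (-0.50). No member passed the size rule in the class as a whole. The median was -0.33 in layer 2/3 and -0.39 in layer 6 corticothalamic neurons, and -0.022 in layer 5 extratelencephalic neurons, where 7 of 13 members lay below 0. In inhibitory neurons the 5 measured members had a median of 0.078 (-0.046 to 0.16), which was 0.20 in nuclei matched on UMIs and -0.066 with at least 30 UMIs and no CPM minimum. In excitatory nuclei matched on UMIs the median was -0.17, with 5 of 16 members above 0. As UMIs per excitatory nucleus, 14 of 16 members were higher in METH, with a median log2 ratio of 0.28 (0.19 to 0.31). This value is the share ratio raised by the higher total UMIs per nucleus in METH.

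**Figure D2:**
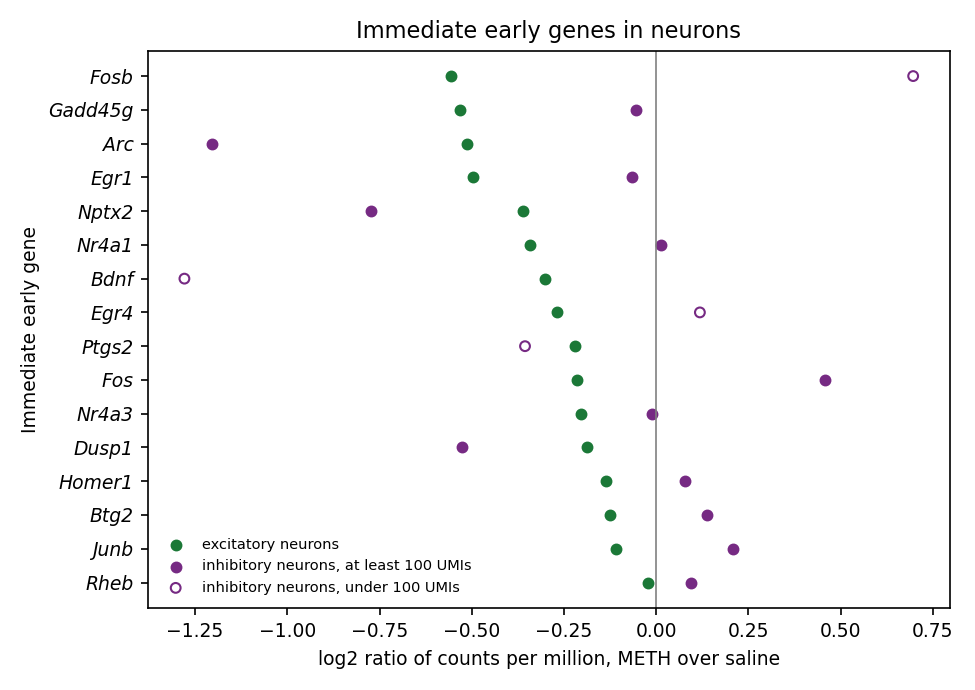
Log2 ratio of CPM, METH over saline, of each immediate early gene measured in excitatory neurons, with the value of the same gene in inhibitory neurons; open circles rest on under 100 UMIs. All 16 excitatory values lie below 0, and those in inhibitory neurons lie on both sides of it.

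Among single genes in excitatory neurons, the highest in METH were the cytoskeletal adaptor Pstpip1 at 44.0 CPM (41.3 to 46.8) against 19.7 (18.0 to 21.5), a log2 ratio of 1.16, the complex I subunit Ndufv3 (1.11), LOC688778 (1.09) and Wipf3 (0.78). The lowest were the small RNA pathway gene Gtsf1 at 105 CPM against 231 (-1.15), the DNA polymerase Polq (-1.23), the RNA-binding protein Pcbp2 (-1.07) and the collagen Col25a1 (-0.87). With neuron clusters weighted alike Pstpip1 was at 0.94 and Wipf3 at 0.59. Thinning gave 1.34 for Pstpip1 and 0.70 for Wipf3. In nuclei matched on UMIs Wipf3 was at 0.87 and Gtsf1 at -0.86. Ionotropic glutamate receptors had a median of -0.029, with Grik3 at 0.36 and Grin2a at -0.33. GABA receptors were at -0.13, with 11 of 12 members below 0 and Gabra2 at -0.22, and at -0.18 in nuclei matched on UMIs; no member passed the size rule. Dopamine receptor and signalling genes were at 0.061, with the phosphodiesterase Pde10a at -0.64 and the G protein subunit Gng7 at 0.50. This median was -0.058 with neuron clusters weighted alike and 0.12 after thinning. Synaptic vesicle and release genes were at -0.041, with Sv2c at 0.45 and Syt4 at -0.37.

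In inhibitory neurons, somatostatin (Sst), the peptide of a dendrite-targeting interneuron class, was lower in METH, at 122 CPM in METH and 319 in saline, a log2 ratio of -1.39 (-1.50 to -1.28), although the Sst subclass took the same share of inhibitory nuclei. In nuclei matched on UMIs Sst was at -0.99. It was 1 of 9 neuropeptide and opioid receptor genes to pass the size rule, which Cck (-0.76), the enkephalin gene Penk (-0.67) and Tac1 (-0.65) did not pass. The list had a median of -0.39, with 7 of 9 members below 0. In nuclei matched on UMIs its median was -0.10, at percentile 6.94, with 3 of 9 above 0.

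The other lowest genes in inhibitory neurons were the protease gene Capn13 at -1.93 (53 and 139 UMIs), Gtsf1 at -1.67 and the protease inhibitor gene Cst3 at -1.24. The highest were Ccdc77 (0.98), the actin regulator Shroom3 (0.93), LOC100360117 (0.93, and 0.40 after thinning) and the glycosyltransferase Alg11 (0.90, and 0.41 after thinning). Cholesterol synthesis genes had a median of 0.14, at percentile 99.7, with 9 of 12 members above 0 and Fdft1 at 0.34, and of 0.23 after matching. GABA receptors were at -0.10, with 12 of 13 members below 0 and Gabrg1 at -0.33, and at -0.22 in nuclei matched on UMIs. Markers of excitatory neurons had a median of -0.37 in inhibitory nuclei over 4 measured genes, but the summed UMIs of all these markers were at -0.012 as a share (-0.078 to 0.054). Markers of astrocytes had a median of -0.30, and their sum was at -0.13.

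Mitochondrially encoded transcripts took a lower share of the METH UMIs in each class compared, apart from mural nuclei, where the interval held 0. The median log2 ratio was -1.01 in oligodendrocytes (-1.12 to -0.86), -0.63 in inhibitory neurons (-0.69 to -0.56), -0.55 in excitatory neurons (-0.57 to -0.50) and -0.54 in astrocytes (-0.65 to -0.44). It was -0.41 in endothelial nuclei, -0.24 in oligodendrocyte precursors and -0.21 in mural nuclei (-0.37 to 0.12). Mt-co2 was at 345 CPM against 705 in oligodendrocytes and at 147 against 225 in excitatory neurons. In nuclei matched on UMIs the medians were -0.73 in oligodendrocytes, -0.47 in inhibitory neurons, -0.20 in excitatory neurons, -0.34 in astrocytes and -0.27 in endothelial nuclei. In precursors the matched median was -0.12, at percentile 15.0, and in mural nuclei 0.042.

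Lists of nuclear genes for translation, respiration and protein folding had medians below 0 in METH neurons, though few members passed the size rule. Ribosomal protein genes had medians of -0.26 in excitatory neurons (22 of 24 below 0, Rps23 at -0.59, Rps15 at -0.49) and -0.29 in inhibitory neurons (34 of 37 below 0, Rps20 at -1.06, Rps27 at -0.78); 0 of 24 and 1 of 37 passed. In nuclei matched on UMIs they were at 0.025 and -0.076, while thinning gave -0.39 in excitatory neurons. Nuclear-encoded oxidative phosphorylation genes were at -0.13 in excitatory neurons, with 26 of 34 below 0, Cox8a at -0.41 and Cox6a1 at -0.40, and at 0.018 after matching. In inhibitory neurons they were at -0.18, with 31 of 38 below 0, and at -0.14 after matching; none passed in either class. Endoplasmic reticulum stress genes were at -0.25 in excitatory and -0.23 in inhibitory neurons, where 0 of 12 and 1 of 14 passed. Their chaperone Hspa5 was at -0.62 in excitatory and -0.97 in inhibitory neurons, and calreticulin (Calr) at -0.47 and -0.67. After matching these list medians were -0.11 and -0.15.

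**Figure D3:**
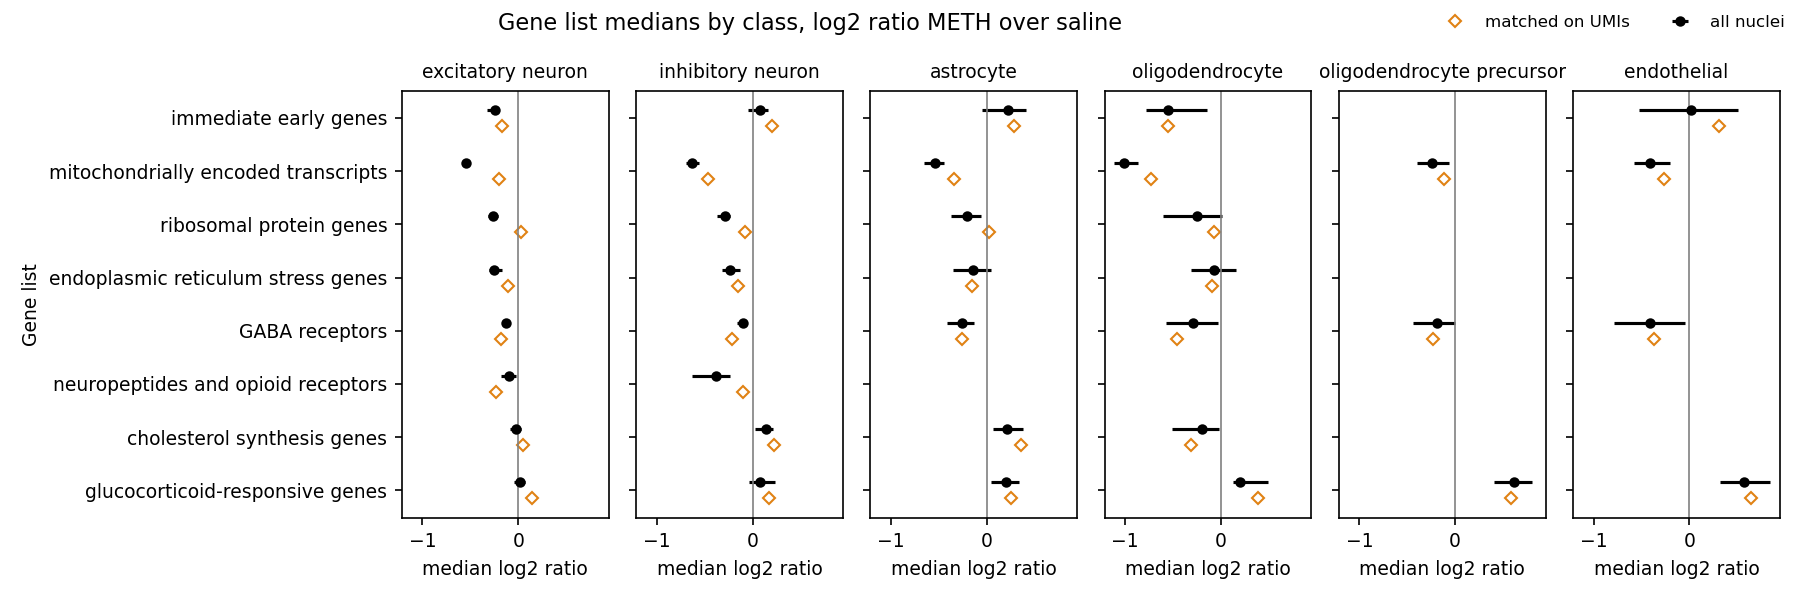
Median log2 ratio, METH over saline, of gene lists in 6 classes, for all nuclei with 95% counting intervals (filled circles) and for nuclei matched on UMIs (open diamonds); lists with under 3 measured members are not drawn. Mitochondrially encoded transcripts lie below 0 in each class, and glucocorticoid-responsive genes lie above 0 in the glial and endothelial classes.

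Glucocorticoid-responsive genes, which the stress hormone receptor induces, had medians above 0 in METH glia and endothelium, though few members passed the size rule (0 of 11 in astrocytes, 1 of 7 in oligodendrocytes, 0 of 4 in precursors and 0 of 4 in endothelium). Their median was 0.20 in astrocytes (10 of 11 above 0, percentile 99.8, Fkbp5 at -0.26), 0.20 in oligodendrocytes (7 of 7), 0.61 in oligodendrocyte precursors (4 of 4, and 0.33 without doublet removal) and 0.56 in endothelial nuclei (4 of 4). The feedback inhibitor of EGF receptors Errfi1 was at 228 CPM in METH and 131 in saline in astrocytes (0.80), at 534 and 268 in oligodendrocytes (0.99) and at 326 and 174 in precursors (0.91, but 0.077 after thinning to 1000 UMIs). Ddit4 was at 0.94 in oligodendrocytes, the transcription factor Zbtb16 at 0.64 in precursors (0.34 after thinning) and 0.55 in endothelium, and Dusp1 at 0.74 in endothelium. After matching on UMIs the medians were 0.25, 0.38, 0.58 and 0.65. In excitatory neurons the median was 0.018, with Fkbp5 at 0.49 and Sult1a1 at -0.62, and in inhibitory neurons 0.081; after matching they were 0.15 (7 of 8 above 0) and 0.17 (4 of 7). Dissociation-response genes, which tissue handling induces, were at 0.26 in astrocytes (4 of 4 above 0, percentile 97.8) and 0.48 in endothelium (3 of 3), and immediate early genes in astrocytes at 0.22 (-0.054 to 0.41). Dusp1 and Nfkbia stand on both the glucocorticoid and the dissociation-response list, and Dusp1 also on the immediate early list. The medians of these lists can therefore share members. These lists, like the others described in the text, were picked from the 36 fixed lists after their values were seen.

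**Figure D4:**
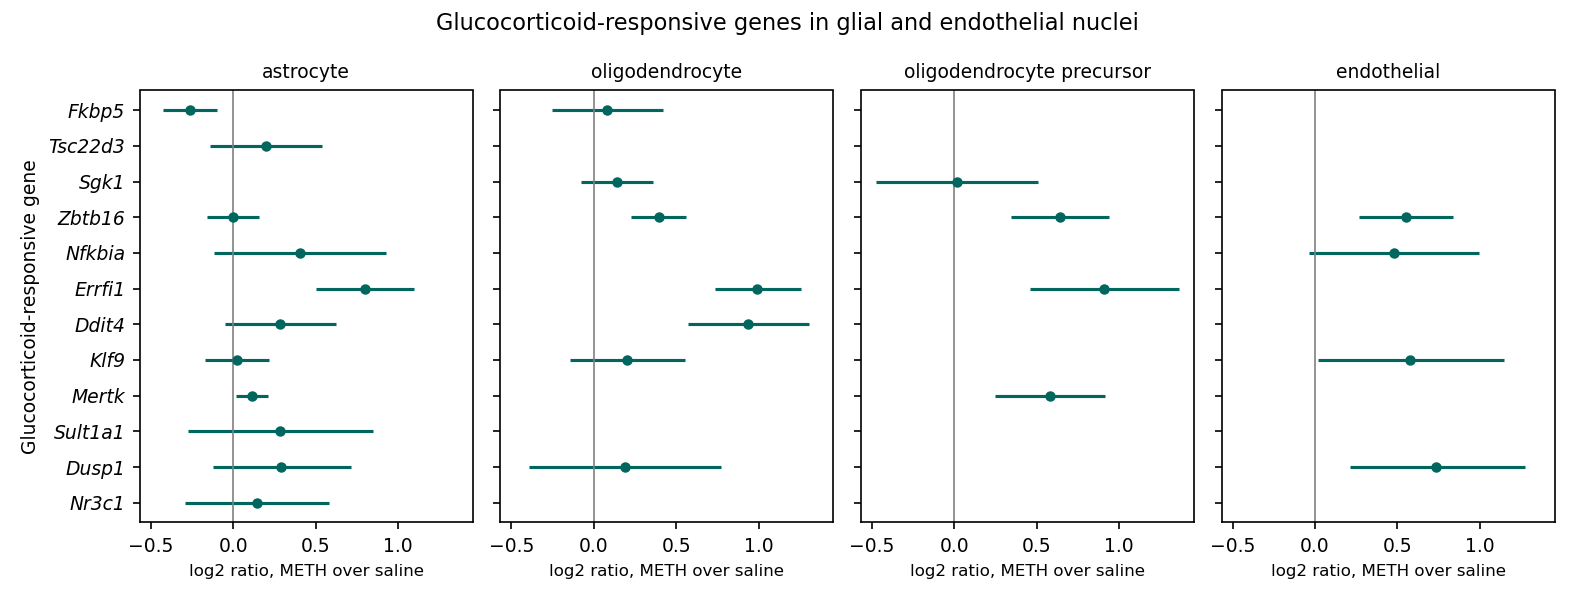
Log2 ratio, METH over saline, of the measured glucocorticoid-responsive genes in astrocytes, oligodendrocytes, oligodendrocyte precursors and endothelial nuclei, with exact 95% counting intervals. Errfi1 lies at 0.80, 0.99 and 0.91 in the glial classes, and Fkbp5 lies below 0 in astrocytes.

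Astrocytes differed most in Pde10a, a cyclic nucleotide phosphodiesterase, at 97.7 CPM in METH and 627 in saline, a log2 ratio of -2.68 (-2.98 to -2.40). Also low were Micalcl (-1.64), the semaphorin receptor Plxna4 (-1.37, and -0.84 without doublet removal) and the adhesion gene Cadm1 (-1.02). The highest were Pld5 at 388 against 122 CPM (1.67), Shroom3 (1.24), the transcription factor Rfx4 (0.94) and the ephrin receptor Ephb1 (0.75). Gfap, an intermediate filament gene that reactive astrocytes raise, was at 170 and 117 CPM (0.53), and the reactivity list had a median of 0.27 over 4 measured members. Cholesterol synthesis genes were at 0.21, with 11 of 13 above 0 and Lss at 0.66, but at -0.054 after thinning. Astrocyte transport and coupling genes were at -0.057, with Slc38a3 at 0.49 and Gjb6 at -0.32, and at 0.042 with TMM scaling. Postsynaptic density genes, which are mainly neuronal, had a median of -0.47 with Dlg2 at -1.05 and Camk2a at -0.89, but -0.099 without doublet removal, -0.22 after matching, -0.30 with at least 1000 genes per nucleus and -0.32 after thinning. Markers of excitatory neurons lay at -0.91 in the same nuclei, and at -0.39 after matching.

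In oligodendrocytes the median of all measured genes was -0.12, and 0.064 with TMM scaling. The highest genes were Rnf220, a ubiquitin ligase, at 154 CPM in METH and 51.6 in saline (1.58), the phosphatase Ptprm (1.23) and Spata22 at 620 and 283 CPM (1.13). Cemip2 was at 1.75, but 1 nucleus held 56.1% of its METH UMIs and it was at 1.15 without the highest nucleus of each library and at -2.23 in matched nuclei. The lowest were Gtsf1 (-2.17), the synaptic gene Olfm1 (-1.38), Tmem132b (-1.23) and Cst3 (-1.15). Myelin genes had a median of -0.17, with Cnp at -0.90 and Ermn at -0.51, and 0.018 with TMM scaling. In precursors, Cst3 was at -1.14, Ipo11 at -1.05 (-0.38 without doublet removal), the ryanodine receptor Ryr2 at -0.80 (-0.24 without it) and the GABA receptor subunit Gabrb1 at -0.79. The splicing factor Srsf4 was at 0.84 and Fam89a at 0.59 (0.16 without doublet removal).

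In endothelial nuclei, the stress-responsive gene Ndrg1 was at 682 CPM in METH and 240 in saline (1.51, 1.08 to 1.95), and the clotting factor carrier Vwf at 711 and 329 (1.11). Also high were Pip5k1b (1.13, and 0.47 after thinning) and Chn2 (1.09). The glucose transporter Slc2a1 was at 0.80 and the amino acid transporter Slc7a5 at 0.52, and the blood-brain barrier list had a median of 0.28 with 8 of 11 members above 0, 2 of which passed the size rule. That median was 0.16 after matching, at percentile 63.1, and 0.50 without doublet removal. The lowest were the neuronal genes Il1rapl2 (-2.50), Lsamp (-1.64), Ak5 (-1.44) and Kcnq3 (-1.20). A single nucleus held 35.0% of the saline UMIs of Il1rapl2, 33.3% of the METH UMIs of Lsamp, 44.1% of those of Ak5 and 43.4% of those of Kcnq3. Il1rapl2 was at -4.26 without doublet removal, -1.65 with centring, -1.29 after thinning and -1.28 with equal weight per nucleus. Kcnq3 was at -2.06 without doublet removal and -0.43 after thinning, and Ak5 at -0.72 after matching. The summed UMIs of excitatory neuron markers in endothelial nuclei were at -0.26 as a share (-0.51 to -0.013). Those of oligodendrocyte markers (-0.35) and astrocyte markers (0.15) had intervals that held 0.

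In mural nuclei, Zbtb16 was at 897 and 436 CPM (1.04) and the contractile kinase Mylk at 378 and 169 (1.16). Il1rapl2 (2.29) and Grm8 (1.05) were also high, but 1 METH nucleus held 75.3% and 51.7% of their UMIs, and without the highest nuclei they were at 0.49 and 0.45. Erbb4 was at -2.08 with 1 saline nucleus holding 74.4% of its UMIs, and at 1.48 in matched nuclei. Meis2 (-1.83), Homer1 (-1.64) and Pde10a (-1.52) were also low. Synaptic adhesion genes had a median of -0.34, with 11 of 12 below 0 and Lrrtm3 at -0.83; it was -0.69 after thinning, -0.56 with equal weight per nucleus and -0.20 as the mean of members. Markers of excitatory neurons were at -0.21 over 3 genes, with an interval that held 0, and their summed UMIs at -0.42 as a share (-0.67 to -0.18).

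Across the 7 classes, the genes described here passed the size rule in at least 3 classes, each lower in METH. Gtsf1 was lower in 4 of the 4 classes where it was measured, Cst3 in 4 of 7, Pde10a in 4 of 6 and the lipid carrier Apoe in 3 of 7. Pde10a was at 0.15 in oligodendrocyte precursors, where the interval held 0. Apoe is abundant in astrocytes, and it passed the rule outside the class where it is highest, at -0.82 in excitatory and -0.91 in inhibitory neurons. Cst3 too was highest in astrocytes, at 481 CPM in METH and 638 in saline (-0.41), and did not pass there. Whether RNA from outside the nucleus carries the ratios of Gtsf1, Cst3 and Apoe was not tested. After matching on UMIs Apoe passed the rule in 0 classes and Cst3 in 2, and after thinning, which discards UMIs and widens the intervals, Gtsf1 passed in 2, Pde10a in 1 and Apoe in 0. Matching keeps fewer nuclei, which widens the intervals too. Matched Cst3 was at -0.88 in excitatory and -0.95 in inhibitory neurons. Its ratio nearest to 0 over the settings run was -0.88 in oligodendrocytes and -0.82 in precursors. Matched Apoe was at -0.38 in excitatory and -0.62 in inhibitory neurons. The thinned ratios of Gtsf1 were -2.28 in oligodendrocytes and -1.90 in astrocytes, and those of Pde10a -3.24 in astrocytes and -0.73 in inhibitory neurons. At a 2-fold size Cst3 and Pde10a passed in 2 classes each.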

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

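Matching on UMIs, equal mix of neuron clusters, the total without the most abundant gene, leaving out the highest nucleus of each gene, the counting of a cluster mostly of 1 library as inhibitory and the naming of subclasses with no lead were chosen after the results were seen. The lower excitatory share (-0.38 to -0.25) and the higher inhibitory share (0.39 to 0.56) kept their direction in each setting run. Among neurons alone they were -0.25 and 0.53, where both shares are complements, so that a fall in either raises the other. With the cluster mostly of 1 library the inhibitory value was 0.56. With at least 1000 genes per nucleus the oligodendrocyte share was 0.25, with an interval that held 0 (-0.054 to 0.56), and the astrocyte share 0.21 (0.0075 to 0.41). At a limit of 1% mitochondrial UMIs the microglia share was -0.47 (-1.09 to 0.13). With subclasses named with no lead needed the layer 2/3 value was 0.024.

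Thinning to 1000 UMIs reversed the log2 ratio of genes per nucleus, to -0.019 in excitatory and -0.019 in inhibitory neurons, -0.053 in astrocytes, -0.14 in oligodendrocytes, -0.015 in precursors, -0.049 in endothelial and -0.043 in mural nuclei, so the higher gene numbers in METH rest on depth. It left the mitochondrial median in excitatory neurons at -0.45, turned the astrocyte cholesterol median to -0.054, and left Gtsf1 past the size rule in 2 classes, Pde10a in 1 and Apoe in 0. Since it discards UMIs these counts can fall with a ratio still past 1.5-fold. In astrocytes Gtsf1 was at -1.90 after thinning and -1.33 before. Over the settings run, the Pde10a ratio nearest to 0 was -0.71 in inhibitory neurons and -1.48 in mural nuclei. Thinned Pde10a was at -3.24 in astrocytes.

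Matching on UMIs moved the immediate early median in excitatory neurons to -0.17, the mitochondrial medians to -0.20 in excitatory neurons, -0.47 in inhibitory neurons and -0.73 in oligodendrocytes, and the neuropeptide median to -0.098. It reversed ribosomal protein genes (0.025) and oxidative phosphorylation genes (0.018) in excitatory neurons, Cemip2 in oligodendrocytes (-2.23), Erbb4 in mural (1.48) and Pde10a in endothelial nuclei (0.20), and Apoe in astrocytes (0.0098). Cst3 passed the size rule in 2 classes and Apoe in 0. Since matching keeps fewer nuclei, such calls can be lost with a ratio still far from 0. Over the settings run, the Cst3 ratio nearest to 0 was -0.88 in oligodendrocytes and -0.82 in precursors. Matched Cst3 was at -0.88 in excitatory and -0.95 in inhibitory neurons.

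With the 2-fold size Cst3 and Pde10a passed in 2 classes each, and Apoe in 0. Apoe passed in 1 class without doublet removal and in 1 with at least 1000 genes. Without doublet removal the glucocorticoid median in precursors was 0.33. TMM scaling gave -0.83 for mitochondrial transcripts and 0.018 for myelin genes in oligodendrocytes, and at least 1000 genes gave -0.75 for the former. Equal weight per nucleus gave -0.34 for immediate early genes. For mitochondrial transcripts in excitatory neurons the equal cluster mix gave -0.61 and the mean of members -0.48. The causes of these shifts, other than the depth effects named, were not tested.

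Of the 78 values of named genes in a class, TMM scaling left 76 within their interval, equal weight per nucleus 72, no doublet removal 68, and thinning and matching 60 each. With at least 1000 genes per nucleus no cluster was named endothelial or mural, so these classes have no value there.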

Other observations

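All tests in this part were chosen after the results were seen, and the conditions on UMIs per nucleus, on single classes and on the spread of members were added after the first values of these tests were known.

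The lower share of excitatory and the higher share of inhibitory nuclei in METH were weighed first. Counting all unnamed nuclei as excitatory left the excitatory ratio at -0.18 (-0.25 to -0.11), so the unnamed clusters do not account for all of it. A loss of excitatory nuclei in preparation stays open and untested, since 1 library per group gives no measure of how recovery varies. A difference in the place of dissection may contribute, since a cluster with Meis1 and Pbx3 had 99.4% of its scaled nuclei from METH, although that cluster was known before the test was written and lies outside both classes. METH treatment itself stays open and untested, because treatment and library are confounded with 1 library per group.

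The lower share of mitochondrial transcripts was weighed against depth and against RNA from outside the nucleus. In nuclei matched on UMIs the median was -0.47 in inhibitory neurons and -0.73 in oligodendrocytes. UMIs per nucleus of these transcripts were lower there too (13.5 against 14.9, and 5.24 against 7.81), although total UMIs per nucleus were higher in METH. This argues against depth as the whole cause in these classes. In excitatory neurons the matched median was -0.20 (-0.23 to -0.13), with 2 of 8 members above 0. UMIs per nucleus were 9.62 against 9.65, with a ratio whose interval held 0, so depth as the whole cause stays open there. For ribosomal protein genes in excitatory neurons the matched median was 0.025 (-0.054 to 0.058), so depth may be the cause. Thinning to 1000 UMIs left -0.39, but it keeps the expected gene shares of each nucleus and so cannot decide this. Less RNA from outside the nucleus may contribute in astrocytes, where oligodendrocyte markers (-0.70) and excitatory markers (-0.51) per nucleus were lower. It stays open in neurons. Oligodendrocyte markers per nucleus were at 0.13 in excitatory and -0.19 in inhibitory neurons, and at -0.39 and -0.65 as a share of UMIs. Astrocyte markers were at 0.43 and 0.33 per nucleus, but lower as a share (-0.092, -0.15 to -0.036, and -0.13, -0.21 to -0.058). Excitatory markers in inhibitory nuclei were at 0.45 per nucleus, and at -0.012 as a share, with an interval that held 0. Per-nucleus values above 0 are share ratios raised by the higher total UMIs per nucleus in METH, so they cannot decide this. In oligodendrocytes, where the mitochondrial median was lowest, less RNA from outside the nucleus stays open too. There astrocyte markers were at 0.10 per nucleus (-0.16 to 0.37) and excitatory markers at -0.13 (-0.43 to 0.17). As a share these markers were at -0.31 and -0.55. An effect of METH was not tested apart from the library.

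The lower immediate early genes in excitatory neurons were weighed last: with the same mix of excitatory clusters in both libraries the median was -0.22 (-0.29 to -0.18), so the mix does not account for all of it. In nuclei matched on UMIs the median stayed below 0, at -0.17 (-0.23 to -0.12) and percentile 0.01 of the random lists. With 5 of 16 members above 0 and 1 library per group, depth as the whole cause stays open. UMIs per nucleus were higher in METH for 14 of the 16 genes (median 0.28). That value is the share ratio raised by the higher total UMIs per nucleus in METH, so it cannot decide between causes. Loss of RNA outside the nucleus from all neurons alike would lower the same genes in inhibitory neurons and stays open: their median there was 0.0004 (-0.15 to 0.11), but 8 lay above 0 and 8 below, from Fosb at 0.70 to Bdnf at -1.28, and their SD of 0.55 exceeds the gap of 0.25 between the medians. A lower activity state of excitatory neurons after repeated METH is a hypothesis that these values leave open. Handling before tissue was taken, the animals and the library differ along with the treatment and were not tested.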
